A study of Mus musculus with 12 samples.

How the data were processed

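Liver RNA of 12 mice was hybridised by the submitters to Affymetrix GeneChip Mouse Exon 1.0 ST arrays, 1 biotin-labelled sample per array. Wild-type and Tiparp knockout mice of a mixed C57BL/6;129Sv background, 8 weeks of age, received corn oil or TCDD at 30 µg per kg, with 3 arrays in each of the 4 groups. The time between dose and collection is not given in the labels. The deposited values are log2 expression values made by the authors with RMA, 1 per probe set and array. The submitters' processing notes name Affymetrix Expression Console, RMA and the build mm9. Versions, the probe set level and the annotation are not given in the sources used here. The values had 2 decimals and ran from 1.05 to 14.16 with array medians of 6.91 to 7.00, and were used as deposited, with no further scaling, filter or pseudocount.

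The table holds 23332 probe sets. A gene table supplied for the platform gave exactly 1 symbol to 14996 of them, several to 1019 and none to 7317. The 14996 stand for 14860 distinct genes. Gene numbers matched 14941 to a RefSeq table of GRCm38.p6, and 0 symbols had to be changed. A gene with several probe sets was represented by the probe set with the highest mean over all arrays. No array was left out, no arrays were identical, and 0 columns came from other series.

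The comparisons, tests, gene lists and rule for naming genes were set before the data were examined, apart from the additions named as such. A group-means model was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (8 residual degrees of freedom, prior degrees of freedom 2.19), followed by contrasts and the default empirical Bayes step. Contrasts were TCDD minus corn oil in each genotype, knockout minus wild-type under each treatment, and the difference between the TCDD effects (the interaction). The TCDD effects of the genotypes share no arrays, but their tests share the residual spread of each probe set. P-values were adjusted by the Benjamini-Hochberg method over all probe sets within each of the 5 comparisons, and an adjusted p below 0.05 was a call. All such adjusted p-values in the text are from limma. Errors marked SE are of the log2 change, from the moderated residual spread of limma, and errors marked SD are of 3 arrays.

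There were 29 gene lists, of which 27 had at least 5 measured members and were tested. The lists of erythroid and sex chromosome genes, with 4 and 2 measured members, were not. Of 454 listed genes 350 were measured. The lists cover AhR, NRF2, CAR and PXR target genes, fatty acid synthesis, lipid uptake and droplets, fatty acid oxidation, cholesterol, bile acids, glucose, the PARP family, NAD metabolism, acute phase, cytokines, interferon, stress response, p53, cell cycle, the clock, sex-biased liver genes, and markers of macrophages, neutrophils, lymphocytes, stellate cells, endothelium, cholangiocytes, and pancreas and fat. They were tested with camera of limma at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. The estimated correlation was -0.0247 for NRF2 antioxidant genes and -0.0131 for male-biased liver genes, both below the preset value. Where these lists lost a call with an estimated correlation, a higher correlation among members was not the reason.

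Genes named in each comparison were Tiparp, then the 6 largest rises and 6 largest falls among called probe sets with 1 symbol and no overlap between the arrays of both groups (for the interaction, called probe sets). Up to 3 called members were added from each list that passed camera or had at least 3 called members, for at most 6 lists. Cyp1a1, Cyp1a2, Cyp1b1, Ahrr and Nqo1 were always named for TCDD. Overlap of calls was compared with the number that independent lists would share. Calls among the neighbours of Tiparp were compared with those among other genes by Fisher's exact test, two-sided. A window of distance was planned, but the RefSeq table is of another build than the notes name, so 100 measured genes on either side were used, in the order of that table.

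Alternatives were robust and trended empirical Bayes, only the arrays of the compared groups, replicate number as a block, quantile normalization again, median centring, dropping the lowest 25% or 50% of probe sets, only probe sets with 1 symbol, array weights, a fold of at least 1.5, an adjusted p below 0.01 and leaving out each array. Chosen after seeing the data were a clock index as a covariate, the wild-type corn oil arrays as control for knockout TCDD, and neighbour counts of 25, 50 and 200. The clock index of an array is made from 6 clock genes that are high together and 4 that are low. The fit was tested on simulated data of 23332 probe sets, in which a log2 change of 1 was recovered in 82.1% of 67 changed probe sets for the wild-type TCDD effect and in 47.8% for the interaction, with 6 false among 146 calls and 8 among 97. A log2 change of 0.5 was recovered in 34.3% and 7.46%. The simulated noise was independent between probe sets and had equal spread in all groups, so these rates need not hold for the real arrays.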

Results

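Hepatic gene expression was measured in 12 mice of a mixed C57BL/6;129Sv background, 8 weeks of age, with an Affymetrix Mouse Exon array for each liver. Wild-type mice and mice lacking Tiparp, a mono-ADP-ribosyltransferase that is induced through the aryl hydrocarbon receptor (AhR) and represses it, received the corn oil vehicle or the dioxin TCDD, a potent AhR ligand, at 30 µg per kg of body weight by intraperitoneal injection. There were 3 arrays, labelled as biological replicates, in each of the 4 groups, and this number limits the precision of every value below. The title of the series names the question, which is how loss of Tiparp alters the sensitivity of the liver to dioxin. Array medians lay between 6.91 and 7.00 on the log2 scale, and arrays of a group correlated with Pearson's r between 0.979 and 0.989 across probe sets, which are not independent. The knockout corn oil arrays lay apart from the others on the main component of variation. Replicates 1 and 2 (scores 45.8 and 36.7) did so more than replicate 3 (17.2), which was closer to wild-type corn oil replicate 3 (7.99). The knockout corn oil arrays had the highest median within-group SD of the 4 groups, 0.164, against 0.129 in wild-type corn oil, 0.136 in wild-type TCDD and 0.140 in knockout TCDD.

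**Figure D1:**
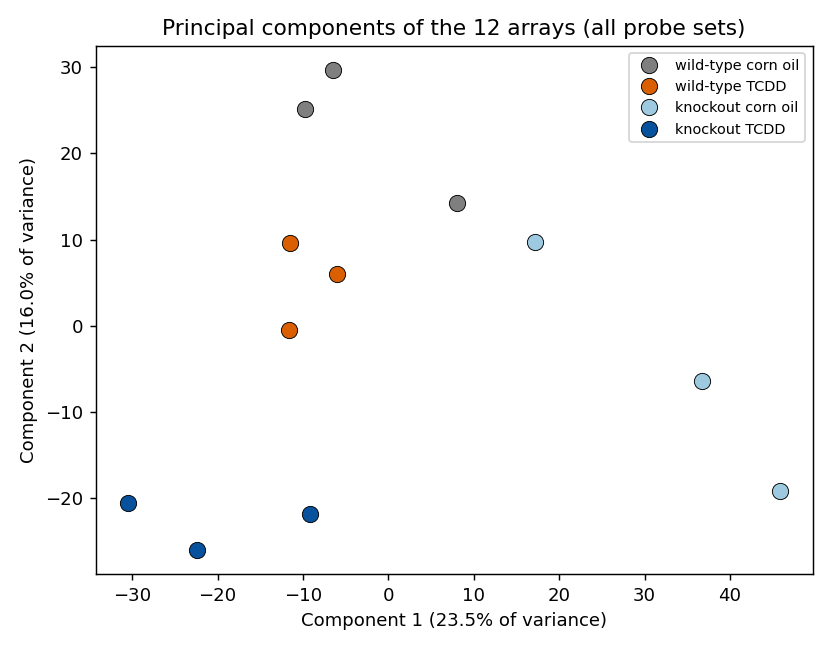
Each point is 1 array, placed by its scores (arbitrary units) on components 1 (23.5% of variance, x axis) and 2 (16.0%, y axis), with the colour giving the group. The knockout corn oil arrays have scores of 17.2 to 45.8 on component 1, and the knockout TCDD arrays have scores of -30.5 to -9.24.

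Tiparp itself (probe set 6898076) was induced by TCDD in wild-type liver, from 7.39 ± 0.05 to 10.52 ± 0.53 (log2, SD, n = 3), a rise of 3.14 ± 0.34 (SE; adjusted p = 0.00935). In the knockout it stood at 6.29 ± 0.76 with corn oil and 6.81 ± 0.11 with TCDD (SD, n = 3), and the change of 0.52 ± 0.34 (SE) did not pass the test (adjusted p = 0.429). Under TCDD the knockout lay below the wild-type by a log2 difference of -3.71 ± 0.34 (SE; adjusted p = 0.0021), with all 3 knockout arrays below all 3 wild-type arrays. Under corn oil the knockout arrays were likewise all below the wild-type arrays, but the difference of -1.09 ± 0.34 (SE) did not pass the test (adjusted p = 0.12). Which part of the transcript the single Tiparp probe set covers is not given in the sources used here. The low residual signal in the knockout therefore does not separate background from a remaining transcript. The wild-type rise was not called without wild-type corn oil replicate 2 (adjusted p = 0.0538), wild-type TCDD replicate 2 (adjusted p = 0.0712) or wild-type TCDD replicate 3 (adjusted p = 0.0556). Its size stayed between 2.98 and 3.44 in all 6 fits that left out 1 array.

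**Figure D2:**
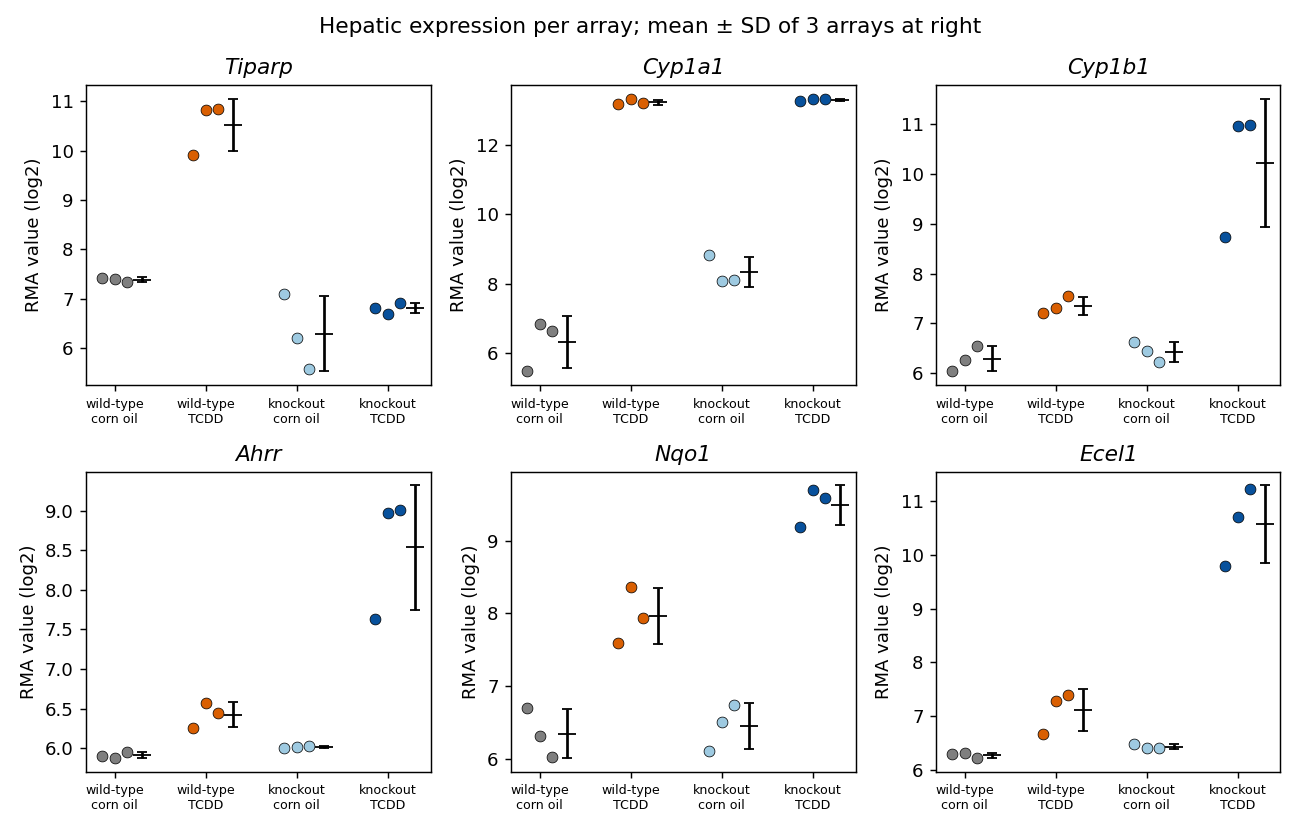
Points are the log2 RMA values (y axis) of single arrays in the 4 groups (x axis), and the bar beside each group is the mean ± SD of 3 arrays. Cyp1a1 reaches 13.24 in wild-type and 13.31 in knockout liver under TCDD, while Cyp1b1, Ahrr and Ecel1 reach 10.22, 8.54 and 10.57 in the knockout against 7.35, 6.42 and 7.11 in the wild-type.

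In wild-type liver all genes called under TCDD rose. Cyp1a1 (probe set 6989422), the classical AhR-induced cytochrome P450, rose from 6.32 ± 0.74 to 13.24 ± 0.07 (SD, n = 3), a log2 change of 6.92 ± 0.32 (SE; 121-fold; adjusted p = 1.59e-05). After Tiparp came Tuba8, an alpha-tubulin (log2 change 2.32), the kinase gene Dclk3 (1.65), the quinone reductase gene Nqo1 (1.62) and the early response gene Ier3 (1.51), with adjusted p-values between 0.00398 and 0.0487. Cyp1a2, a related P450 with high expression in liver, rose by 1.05 ± 0.14 (SE; adjusted p = 0.023). The values for Cyp1b1 (1.06 ± 0.49) and for the AhR repressor Ahrr (0.51 ± 0.30), both with SE, did not pass the test (adjusted p = 0.692 and 0.781). Their wild-type arrays did not overlap. Cyp1b1 read 7.20 to 7.55 under TCDD against 6.05 to 6.55 under corn oil, and Ahrr 6.26 to 6.57 against 5.88 to 5.95. The residual spread behind these SE also includes knockout TCDD, with SDs of 1.29 for Cyp1b1 and 0.79 for Ahrr. The missed tests therefore do not show that induction was absent. In all, 27 of 23332 probe sets were called higher and 0 lower by limma, while 966 were higher and 732 lower at an unadjusted p under 0.05. The count was 9 and 15 without wild-type corn oil replicates 2 and 3, and 12, 6 and 7 without wild-type TCDD replicates 1, 2 and 3. Cyp1a1 and Ier3 were called in each of the 6 fits that left out 1 array, whereas the other 6 called genes named here, Tiparp and Srxn1 included, lost the call in at least 1 of them.

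AhR target genes rose together in the wild-type. Of 13 measured members, 6 were called higher (Cyp1a1, Cyp1a2, Nqo1, Ugdh, Pmm1 and Nfe2l2) and 0 lower, and 9 were higher when adjusted over the list alone. Their median log2 change was 0.86 (camera adjusted p = 3.14e-20, and adjusted p = 0.00106 with an estimated correlation). NRF2 antioxidant genes had 2 of 10 measured members called higher, Nqo1 and the sulfiredoxin gene Srxn1 (log2 change 1.03 ± 0.12, SE; adjusted p = 0.00938). With 2 also higher when adjusted over the list alone, the list passed (camera adjusted p = 0.000342, and adjusted p = 0.035 with an estimated correlation). Nqo1 belongs to both lists. Endothelial cell markers moved the other way. None of the 9 was called over all genes, and 4 were lower when adjusted over the list alone. All 9 values were below 0, and the median was -0.25 (camera adjusted p = 1.07e-07, and adjusted p = 0.035 with an estimated correlation).

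Another 8 lists passed camera in the wild-type with the preset correlation and lost the call with an estimated one, and no member of any of them was called over all genes. Adjusted over the list alone, 1 p53 target gene and 1 stellate cell and matrix gene were lower, and the other 6 lists had 0 calls. Fatty acid oxidation and ketogenesis genes had a median of 0.27 over 17 members (camera adjusted p = 2.12e-05, but adjusted p = 0.434 with an estimated correlation). Fatty acid synthesis genes (camera adjusted p = 0.0233), cholesterol synthesis genes (0.0294), p53 target genes (0.0347), cell cycle genes (0.0262) and macrophage and Kupffer cell markers (0.0113) had medians below 0, each with an adjusted p of 0.666 with an estimated correlation. Stellate cell and matrix genes (camera adjusted p = 0.00576; 0.447 with an estimated correlation) and male-biased liver genes (0.00969; 0.0926 with an estimated correlation) also had medians below 0. Each of these 8 lists lost its camera call in at least 1 of the 6 fits that left out an array, and medians went above 0 for cholesterol synthesis (0.06) and macrophages and Kupffer cells (0.05) without wild-type TCDD replicate 1, and for p53 targets (0.03) without wild-type corn oil replicate 3.

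In knockout liver TCDD raised many of the same AhR targets and others besides. Cyp1a1 rose from 8.34 ± 0.43 to 13.31 ± 0.04 (SD, n = 3), a log2 change of 4.97 ± 0.32 (SE; 31.3-fold; adjusted p = 6.29e-05). Cyp1b1, a P450 of oestrogen and hydrocarbon metabolism, rose by 3.79 ± 0.49 (13.8-fold), Nqo1 by 3.04 ± 0.25 (8.21-fold), Ahrr by 2.52 ± 0.30 (5.74-fold) and Cyp1a2 by 0.85 ± 0.14 (1.80-fold), each with SE. Large rises outside that list came from the metalloprotease gene Ecel1 (4.14 ± 0.30), the fatty acid binding protein gene Fabp12 (4.11 ± 0.36), Dclk3 (3.35 ± 0.20) and the phosphate transporter gene Slc34a2 (3.29 ± 0.48), with adjusted p-values up to 0.00507. Among the falls were the growth factor gene Nrg4 (-2.90 ± 0.41), the glucocorticoid-responsive co-chaperone gene Fkbp5 (-2.53 ± 0.37) and the lysophospholipid transporter gene Mfsd2a (-2.50 ± 0.46). Falls were also seen for the amino acid transporter gene Slc43a1 (-2.15 ± 0.25), the kinase gene Plk3 (-2.06 ± 0.36) and the clock gene Per1 (-1.81 ± 0.31), with adjusted p-values up to 0.0143. The knockout corn oil means of Nrg4 (9.80), Fkbp5 (10.30), Mfsd2a (11.13), Slc43a1 (9.68), Plk3 (11.10) and Per1 (9.31) were each the highest of the 4 group means.

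For the knockout 1303 probe sets were called, 516 higher and 787 lower, of which 813 changed at least 1.5-fold. The prevailing direction depended on the setting, since quantile normalization of the deposited values gave 664 higher and 458 lower, median centring 639 and 536, and an adjusted p below 0.01 gave 170 and 123. The count was 822, 543 and 2004 without knockout corn oil replicates 1, 2 and 3, and 583 and 435 without knockout TCDD replicates 1 and 3. Against the wild-type corn oil arrays, a control chosen after seeing the data, the knockout TCDD arrays gave 533 calls, 293 of them among the 1303. Of the 23 called genes named for this comparison, 11 were called against that control and 12 were not, the latter including Slc34a2 and the 6 falls of Nrg4, Fkbp5, Mfsd2a, Slc43a1, Plk3 and Per1. Among the same 23 genes, 19 were called in each fit that left out 1 array, and the exceptions were Tek, Oit3, Ccnd1 and Mcm4.

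**Figure D3:**
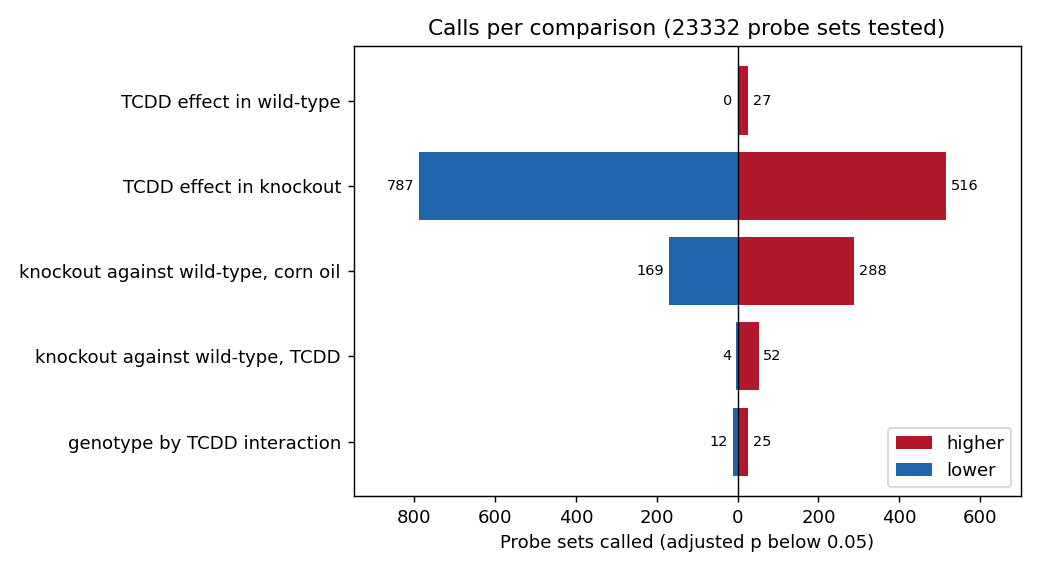
Horizontal bars give the number of probe sets (x axis, starting at 0 and running both ways) called higher (red, right) or lower (blue, left) in each of the 5 comparisons (y axis). TCDD gave 27 calls in the wild-type and 1303 in the knockout, and the knockout differed from the wild-type at 457 probe sets under corn oil and at 56 under TCDD.

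AhR target genes also rose as a group in the knockout. Of the 13 members, 10 were called higher and 0 lower, with 10 also when adjusted over the list alone and a median of 1.78 (camera adjusted p = 2.63e-19, and adjusted p = 0.00126 with an estimated correlation). Aldh3a1 (0.10), Cyp2s1 (0.15) and Xdh (0.08) were the members not called. NRF2 antioxidant genes had 4 of 10 members called higher, which were Nqo1, Srxn1 (1.97 ± 0.12, SE), the pentose phosphate gene Pgd (1.00 ± 0.12, SE) and Gclc, the catalytic subunit of the enzyme that limits glutathione synthesis (2.26 ± 0.28, SE). Gclc was lower in the knockout than in the wild-type under corn oil (-1.32; adjusted p = 0.0473), and against wild-type corn oil its change was 0.94 and not called (adjusted p = 0.123). Adjusted over the list alone, 4 were higher and 1 lower. The list passed camera (adjusted p = 0.00111) but not with an estimated correlation (adjusted p = 0.0526). Of 9 endothelial cell markers, 5 were called lower (6 when adjusted over the list alone), among them the scavenger receptor genes Stab1 and Stab2 (-0.54 ± 0.08 and -0.59 ± 0.09, SE), Tek (-0.58 ± 0.13, SE) and Oit3 (-0.58 ± 0.12, SE). Their median was -0.54 (camera adjusted p = 7.21e-05, but adjusted p = 0.12 with an estimated correlation).

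Cell cycle genes had 3 of 20 members called lower in the knockout, both over all genes and adjusted over the list alone. These were the G1 cyclin genes Ccne1 (-1.26 ± 0.15, SE) and Ccnd1 (-1.07 ± 0.23, SE) and the replication gene Mcm4 (-0.87 ± 0.16, SE), while the list as a whole did not pass (camera adjusted p = 0.27). Against wild-type corn oil in place of knockout corn oil, none of the 3 was called: Ccne1 changed by -0.12 (adjusted p = 0.747), Mcm4 by -0.59 (adjusted p = 0.0894) and Ccnd1 by 0.18, with the opposite sign (adjusted p = 0.742). Genes of the endoplasmic reticulum and integrated stress response had 0 of 15 members called and 4 lower when adjusted over the list alone, with a median of -0.31 (camera adjusted p = 0.0143, but adjusted p = 0.821 with an estimated correlation). Lymphocyte markers had 0 of 11 members called, 0 when adjusted over the list alone, and a median of 0.15 (camera adjusted p = 0.0317, but adjusted p = 0.785 with an estimated correlation). Glucose metabolism genes had 2 members called higher and 1 lower of 13, with the same numbers when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.648).

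The responses of both genotypes overlapped among the strongest genes. Of the 27 probe sets called in the wild-type, 23 were also called higher in the knockout and 0 lower, where independent lists would share 0.597. The 4 others were Tiparp, Ier3 (0.50 in the knockout; adjusted p = 0.0566), Unc93a (0.13; adjusted p = 0.699) and Lrrc8c (0.17; adjusted p = 0.368), of which Unc93a and Lrrc8c are named after their values were seen. Among the 27, 16 had the larger change in the knockout. Both call lists use the same residual spread per probe set and so are not independent, which makes 0.597 only a rough baseline. Over all 23332 probe sets the changes in both genotypes correlated with r = 0.174 across probe sets, which are not independent, and the comparisons share no arrays. Of the 1303 probe sets called in the knockout, 791 (60.7%) had the same sign in the wild-type, against 51.7% of all probe sets. These were 383 of the 516 rises (median wild-type change 0.16) and 408 of the 787 falls (median -0.01). Over all 1303 the wild-type had a median absolute log2 change of 0.147, against 0.68 in the knockout. These probe sets were selected by their change in the knockout, which favours the larger median there. Over all 23332 probe sets, with no selection, the medians were 0.103 in the wild-type and 0.16 in the knockout. A median absolute change also grows with the spread within groups and with any shift of the control arrays. The median within-group SD was 0.132 in the wild-type groups and 0.151 in the knockout groups. These medians alone therefore do not show a larger response to TCDD in the knockout.

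**Figure D4:**
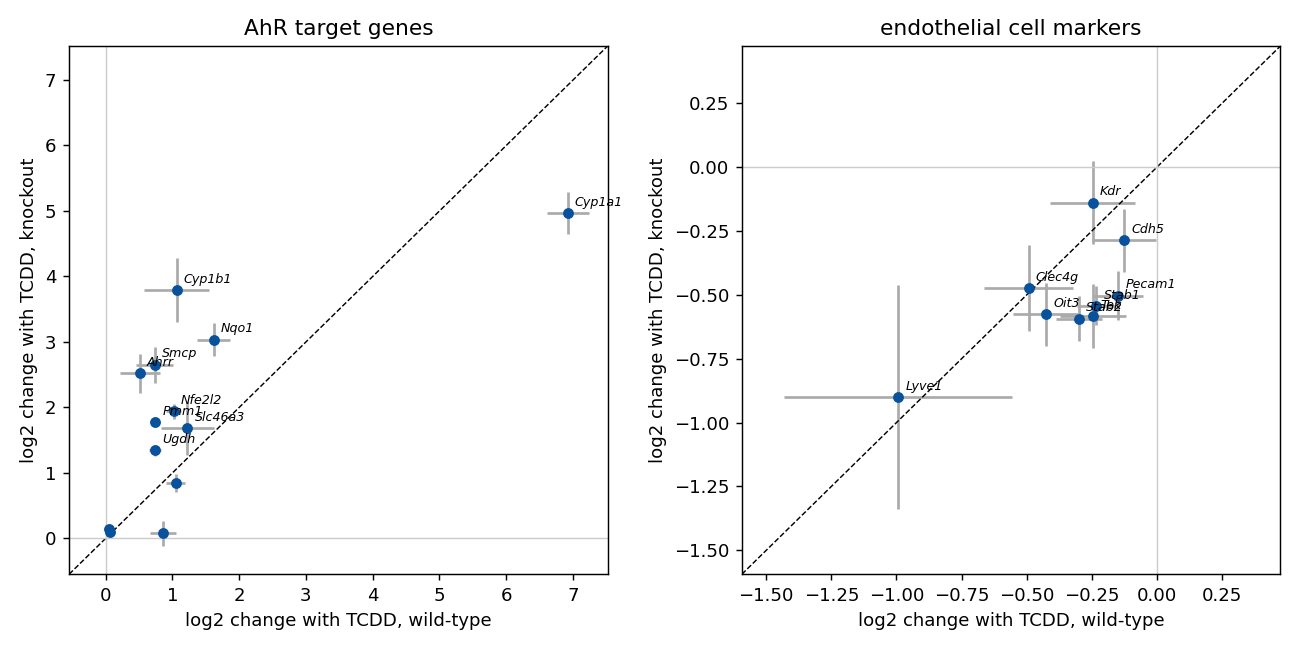
Each point is 1 gene of the AhR target list (left) or the endothelial marker list (right), with its log2 change under TCDD in the wild-type on the x axis and in the knockout on the y axis, bars giving SE and the dashed line marking equal change. Cyp1a1 lies below the line (6.92 and 4.97), Cyp1b1 (1.06 and 3.79) and Ahrr (0.51 and 2.52) lie above it, and all 9 endothelial markers are below 0 in both genotypes.

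With corn oil alone, knockout liver differed from wild-type liver at genes in both directions. The metalloprotease gene Mme (neprilysin) was lower by a log2 difference of -3.34 ± 0.40 (SE; adjusted p = 0.0204). Also lower were Ddc, the aromatic amino acid decarboxylase (-2.14 ± 0.47), the glycogen-targeting phosphatase subunit gene Ppp1r3c (-2.12 ± 0.33), the ubiquitin ligase gene Rnf125 (-1.94 ± 0.27), the tight junction gene Cldn1 (-1.80 ± 0.24) and Sdr9c7 (-1.74 ± 0.32). Higher in the knockout were the ion channel gene Asic5 (2.51 ± 0.33), the cytokine signalling inhibitor gene Cish (2.33 ± 0.34), the phosphatidate phosphatase gene Lpin1 (2.25 ± 0.30). So were the glycolysis regulator gene Pfkfb3 (2.17 ± 0.42), Mfsd2a (2.11 ± 0.46) and Nrg4 (2.09 ± 0.41), all with SE and adjusted p-values between 0.0204 and 0.0497. Cyp1a1 was also higher in the knockout, by 2.02 ± 0.32 (SE; adjusted p = 0.0278), and so was Xdh, by 0.98 ± 0.19 (SE; adjusted p = 0.042), both AhR target genes named here after their values were seen. The list itself, with 2 of 13 members called higher, and 2 higher and 1 lower when adjusted over the list alone, did not pass (camera adjusted p = 0.891).

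Under corn oil 457 probe sets were called, 288 higher and 169 lower in the knockout, but quantile normalization gave 212 higher and 219 lower, and median centring 195 higher and 212 lower. The count fell to 11, 1 and 224 without wild-type corn oil replicates 1, 2 and 3, and moved to 46, 7 and 1624 without knockout corn oil replicates 1, 2 and 3. A limma fit of the 2 corn oil groups alone called 0 probe sets (3842 at an unadjusted p under 0.05). All 18 genes named for this comparison by the rule lost their call in at least 1 fit that left out an array. Of 345 called genes outside the clock list, 171 (49.6%) differed between genotypes in the same direction under TCDD, against 53.4% of all 14860 genes.

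Several lists were higher in the knockout under corn oil with the preset correlation, and none kept its call with an estimated one. Genes of the endoplasmic reticulum and integrated stress response had 3 of 15 members called higher, which were the chaperone gene Dnajb9 (0.95 ± 0.18, SE), Ppp1r15a (0.60 ± 0.13, SE) and the transcription factor gene Atf4 (0.55 ± 0.12, SE). Another count, adjusted over the list alone, had 11 higher (median 0.55; camera adjusted p = 8.07e-05, but adjusted p = 0.764 with an estimated correlation). Acute phase genes had 0 of 18 members called over all genes and 5 higher when adjusted over the list alone. All 18 values were above 0, with a median of 0.25 (camera adjusted p = 0.00027, but adjusted p = 0.882 with an estimated correlation). Saa3, an acute phase gene named after its values were seen, read 13.86 and 13.76 on knockout corn oil arrays 1 and 2 and 9.91 on array 3, against 7.88 to 10.36 on the wild-type corn oil arrays. Cytokines and NF-kB targets had 1 of 15 members called higher, the adhesion molecule gene Vcam1 (0.96 ± 0.20, SE), and 5 when adjusted over the list alone (camera adjusted p = 0.00238, but adjusted p = 0.764 with an estimated correlation). Interferon-stimulated genes had a median of 0.44 over 17 members, none of them called (camera adjusted p = 0.0422, but adjusted p = 0.89 with an estimated correlation). Male-biased liver genes had a median of -0.43 over 6 members, none of them called over all genes and 2 lower when adjusted over the list alone (camera adjusted p = 0.0486, but adjusted p = 0.757 with an estimated correlation). Fatty acid synthesis genes had Lpin1 called higher and Acacb (-0.85 ± 0.15, SE) and Agpat2 (-0.46 ± 0.09, SE) lower among 18 members, and the list did not pass (camera adjusted p = 0.057). Markers of other cells had medians above 0 in the same comparison, at 0.30 for neutrophils, 0.28 for macrophages and Kupffer cells, 0.17 for endothelium, 0.12 for stellate cells and matrix and 0.04 for lymphocytes. Of these, 2 of 11 neutrophil markers and 1 of 12 macrophage and Kupffer cell markers were called higher, and 0 in the other lists. Adjusted over the list alone, 4 neutrophil markers were higher, and 1 each for macrophages and Kupffer cells, endothelium, and stellate cells and matrix. The neutrophil list did not pass (camera adjusted p = 0.0546).

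Under TCDD most probe sets called between the genotypes were higher in the knockout. Ecel1 was higher by 3.46 ± 0.30, Gadd45b, a stress-induced growth arrest gene, by 2.67 ± 0.20 and Fabp12 by 2.29 ± 0.36. Ahrr was higher by 2.11 ± 0.30, the pro-apoptotic BH3 gene Bcl2l11 by 2.04 ± 0.22 and the sialyltransferase gene St8sia1 by 2.02 ± 0.18, all with SE and adjusted p-values between 0.000813 and 0.036. Besides Tiparp, Mme (-3.13 ± 0.40, SE; adjusted p = 0.0136) and Irf2bp1 (-0.44 ± 0.06, SE; adjusted p = 0.0211) were lower. Cyp1a1 differed by 0.07 ± 0.32 (SE; adjusted p = 0.958). All its TCDD arrays read 13.19 to 13.34, where the highest values of those arrays were 14.07 to 14.16. Whether its signal was limited at that level was not tested. In all, 52 probe sets were called higher and 4 lower, while 1000 were higher and 1774 lower at an unadjusted p under 0.05 in limma. The count of calls was 32, 32 and 26 without wild-type TCDD replicates 1, 2 and 3 and 35 and 21 without knockout TCDD replicates 2 and 3. A fit of the 2 TCDD groups alone called 0 (2864 at an unadjusted p under 0.05). Of the 11 called genes named here by the rule, Tiparp, Ecel1, Gadd45b, Bcl2l11 and St8sia1 were called in each fit that left out 1 array.

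AhR target genes stood higher in the knockout than in the wild-type under TCDD, with 4 of 13 called higher, namely Ahrr, Smcp (1.79 ± 0.27, SE), Nqo1 (1.52 ± 0.25, SE) and Pmm1 (1.10 ± 0.08, SE). There were 7 higher when adjusted over the list alone, and all 13 values were above 0 (median 0.27; camera adjusted p = 8.39e-11, and adjusted p = 0.00959 with an estimated correlation). NRF2 antioxidant genes had 3 of 10 called higher, Nqo1, Srxn1 and Pgd, and 3 when adjusted over the list alone (camera adjusted p = 0.0126, but adjusted p = 0.138 with an estimated correlation). Stellate cell and matrix genes had 0 of 13 called over all genes and 7 higher when adjusted over the list alone, with a median of 0.33 (camera adjusted p = 2.08e-08, but adjusted p = 0.138 with an estimated correlation). Interferon-stimulated genes had a median of 0.50 over 17 members (camera adjusted p = 3.98e-07, but adjusted p = 0.543 with an estimated correlation). Lymphocyte markers (median 0.13; camera adjusted p = 0.00342; 0.422 with an estimated correlation) and macrophage and Kupffer cell markers (median 0.26; camera adjusted p = 0.0126; 0.881 with an estimated correlation) also passed only with the preset correlation. Fatty acid oxidation and ketogenesis genes were the list with a median below 0, at -0.23 over 17 members (camera adjusted p = 0.00342, but adjusted p = 0.709 with an estimated correlation). No member of these 4 lists was called over all genes, and 1 fatty acid oxidation gene was lower when adjusted over the list alone.

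The difference between the TCDD responses of the genotypes was tested directly by the interaction. The response was larger in the knockout for Ecel1, by 3.30 ± 0.43, and for Tnfaip2 (2.38 ± 0.28), Gadd45b (2.09 ± 0.29) and the receptor gene Tnfrsf19 (1.90 ± 0.28), with SE. Rnf125 rose from 11.10 to 13.28 in the knockout and had means of 13.04 and 12.34 in the wild-type, where the change of -0.70 was not called (interaction 2.88 ± 0.38, SE). Gm7180 differed by 2.06 ± 0.28 (SE). On the other side were the cyclin gene Ccne1 (-1.39 ± 0.22), the transcription factor gene Klf10 (-1.36 ± 0.19) and Znrd1 (-1.27 ± 0.17), with SE. The response was likewise more negative in the knockout for Slc35a4 (-1.11 ± 0.15), Yrdc (-1.09 ± 0.17) and Dda1 (-0.92 ± 0.12), with SE. The means of these 6 genes were highest in knockout corn oil. Adjusted p-values of these 12 genes lay between 0.0242 and 0.0484. For Tiparp the interaction of -2.62 ± 0.49 (SE) missed the threshold (adjusted p = 0.0742), as did that of Cyp1a1 (-1.95; adjusted p = 0.0973) and of Cyp1b1 (2.72; adjusted p = 0.116). In wild-type and knockout the Cyp1a1 means were 6.32 and 8.34 under corn oil, and 13.24 and 13.31 under TCDD. The negative value for Cyp1a1 thus came mainly from the corn oil arrays.

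The interaction was called at 37 probe sets, 25 with a positive and 12 with a negative sign, against 51 and 10 after quantile normalization. Negative signs were the more frequent without the lowest 25% of probe sets (66 positive and 83 negative) or the lowest 50% (135 and 261), with 1 symbol (60 and 102), with array weights (233 and 460) and without knockout corn oil replicate 3 (156 and 390). Leaving out 1 array gave 1, 0 and 0 calls for wild-type corn oil replicates 1, 2 and 3 (2699 and 3428 at an unadjusted p under 0.05 for replicates 2 and 3). It gave 24, 1 and 4 calls for wild-type TCDD, 43, 3 and 546 for knockout corn oil and 59, 91 and 5 for knockout TCDD. All 14 genes named by the rule lost the call in at least 1 of these 12 fits. AhR target genes had 1 of 13 members called, Pmm1 (1.04 ± 0.11, SE; adjusted p = 0.0242). Adjusted over the list alone 7 were positive and 2 negative (median 0.60; camera adjusted p = 2.81e-05, but adjusted p = 0.0876 with an estimated correlation). NRF2 antioxidant genes had 1 of 10 called, Pgd (0.88 ± 0.12, SE), with 4 positive when adjusted over the list alone. Their median of -0.01 differed in sign from their mean of 0.35 and from the test (camera adjusted p = 0.0371, but adjusted p = 0.302 with an estimated correlation). Genes of the endoplasmic reticulum and integrated stress response (median -0.45; camera adjusted p = 0.00209), lymphocyte markers (0.20; camera adjusted p = 0.00924) and stellate cell and matrix genes (0.24; camera adjusted p = 0.00242) passed with the preset correlation, each with an adjusted p of 0.498 with an estimated correlation and 0 members called over all genes. Adjusted over the list alone, 7 stress response genes were negative, 1 lymphocyte marker was positive and 0 stellate cell and matrix genes were called.

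Lipid handling was of interest because the title of the series names fat accumulation in the liver. The list of lipid uptake, droplets and export did not pass camera in any of the 5 comparisons (lowest adjusted p = 0.0563, in the wild-type, median 0.12 over 16 members). Within fatty acid synthesis, Acacb, the mitochondrial acetyl-CoA carboxylase, went from 10.26 to 9.86 with TCDD in the wild-type (not called) and from 9.41 to 10.47 in the knockout, with an interaction of 1.47 ± 0.21 (SE; adjusted p = 0.0316). Within fatty acid oxidation, Cyp4a14 had log2 changes of 3.19 in the wild-type and -2.26 in the knockout, neither called (adjusted p = 0.469 and 0.193), and is named after its values were seen. Genes beside Tiparp on chromosome 3 were examined because DNA of the stem cell strain can stay beside a targeted gene in a mixed background. Among the 100 measured genes on either side, in the order of the GRCm38.p6 RefSeq table, 5 of 200 (2.50%) were called under corn oil against 339 of 14632 other genes (2.32%; odds ratio 1.08, 95% interval 0.345 to 2.59, Fisher's exact test, two-sided p = 0.811). The 5 were Aadac, Mme, B3galnt1, Asic5 and Ssr2, at 13 and 6 measured genes on one side and 17, 38 and 98 on the other, of which Aadac, B3galnt1 and Ssr2 are named after their values were seen.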

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

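Tests of a lower share of hepatocytes, of a genotype effect present under both treatments and of both explanations for the neighbours of Tiparp were chosen only after the result was seen.

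The TCDD response differed between genotypes, by the interaction test, at 37 probe sets. By size of the log2 difference (knockout minus wild-type) these include Ecel1 (3.30), Rnf125 (2.88), Tnfaip2 (2.38), Gadd45b (2.09), Gm7180 (2.06), Tnfrsf19 (1.90), St8sia1 (1.86), Acacb (1.47), Pmm1 (1.04) and Pgd (0.88). Negative differences were Ccne1 (-1.39), Klf10 (-1.36), Znrd1 (-1.27), Slc35a4 (-1.11), Yrdc (-1.09) and Dda1 (-0.92). Of the 37, 23 had opposite directions in the genotypes and 14 the same. Among lists, the difference had a median of 0.60 for AhR target genes, -0.01 for NRF2 antioxidant genes (mean 0.35), -0.45 for the endoplasmic reticulum and integrated stress response, 0.20 for lymphocyte markers and 0.24 for stellate cell and matrix genes. None of the 5 lists kept its call with an estimated correlation. Of 100 drawn splits of the 200, which exchange genotype within a treatment, 3 gave at least as many calls as the real 37, the real one included. Their basis is no genotype difference under either treatment and not the absence of an interaction, so chance is not excluded for the interaction itself. The highest other split gave 96 calls. It exchanged the genotype labels of all 6 TCDD arrays and of 0 corn oil arrays, so it tests the sum of the genotype differences under both treatments in place of their difference. Another split that moved 2 TCDD labels gave 42.

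For the comparisons of 3 against 3 arrays, 10 splits are too few for a share under 0.05. The real grouping gave 27 calls for TCDD in the wild-type (highest other split 0, and 1 of the 10 splits as many), 1303 in the knockout (highest other 1, and 1 of 10 as many), 457 between genotypes under corn oil (highest other 3, and 1 of 10 as many) and 56 under TCDD (highest other 1, and 1 of 10 as many).

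The knockout corn oil arrays stood apart from the wild-type corn oil arrays. The tables argue against a genotype effect present under both treatments as the whole cause for the called genes as a set. The median share of their corn oil difference found between the TCDD groups was -0.00331 (95% bootstrap interval over genes -0.0380 to 0.0231). That interval takes genes as independent, which they are not, and leaves out the spread between animals, so it is too narrow. A lower share of hepatocytes may contribute and stays open, as the medians of all 5 lists of other cells were above 0, at 0.17 for endothelium, but the lymphocyte median of 0.04 was close to that of all probe sets (0.03), its camera test pointed down, and 0 of the 5 lists passed camera (lowest adjusted p = 0.0546). Of the 457 calls, 4 of the 6 removals of 1 corn oil array left few (11 and 1 without wild-type replicates 1 and 2, and 46 and 7 without knockout replicates 1 and 2), while there were 224 without wild-type replicate 3 and 1624 without knockout replicate 3, which is not what 1 deviating array predicts but does not exclude it. A different phase of the daily clock stays open too, since phase is confounded with the groups. Of the called genes outside the clock list 49.6% kept their direction under TCDD, against 53.4% of all genes. The 95% interval of 44.2% to 55.0% for the called genes likewise takes genes as independent.

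TCDD gave many more calls in the knockout than in the wild-type. Less spread within the knockout groups was not seen, as their median within-group SD was 0.151 against 0.132 in the wild-type groups. The fit shares 1 residual spread over all groups, and the median SE was 0.135 for both TCDD effects. With only the arrays of the compared groups, 184 probe sets were called in the knockout and 13 in the wild-type. A part played by the higher knockout spread was not tested. A shift of the knockout corn oil arrays, from which the changes are measured, stays open. For the genes that rose, a median share of 0.724 of the change remained against wild-type corn oil (quartiles 0.371 and 0.975), and for those that fell, 0.377 (quartiles 0.165 and 0.623). Both changes use the same knockout TCDD arrays, and the genes were selected by their change from knockout corn oil. The share to be met without a shift is therefore not known, and these shares decide nothing. Against that control 208 of the 516 and 85 of the 787 were called. These counts have the same limits, so whether part of the knockout response belongs to its control arrays stays open. For Ecel1, Ahrr, Nqo1 and Pmm1 no shift of the control arrays was seen, as their corn oil means were alike (6.27 and 6.43, 5.91 and 6.02, 6.35 and 6.45, 6.82 and 6.88 in wild-type and knockout). These genes were called higher in the knockout than in the wild-type under TCDD. For Ahrr that call was lost in 5 of the 6 fits that left out 1 array (adjusted p up to 0.0925). For Nqo1 it was lost in 4 of the 6 (adjusted p up to 0.1725), and neither gene was called in the interaction.

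Among the neighbours of Tiparp on chromosome 3, 5 of 200 differed between genotypes under corn oil. Whole-liver differences of the knockout corn oil arrays are argued against for these 5 as a set but not for each, since a median share of 0.631 of their difference remained under TCDD, above 99.97% of 10000 random sets, while the other 340 called genes had a median of -0.00527. Of the 5, Mme alone was called under TCDD, and B3galnt1 (0.73 under corn oil, 0.30 under TCDD) and Ssr2 (0.61 and 0.08) kept less of their difference. Flanking DNA of the stem cell strain stays open, because the odds ratio of 1.08 (95% interval 0.345 to 2.59) is compatible with more and with fewer calls than elsewhere. An effect of the loss of Tiparp itself on these genes was not tested.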

How the results depend on the processing

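The fits with the clock index, the wild-type corn oil control for knockout TCDD and the neighbour counts were chosen only after the data were seen. Causes were not tested except where fewer arrays, fewer probe sets or a stricter threshold make the change by construction.

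Leaving out 1 array gave 6 to 19 calls for TCDD in the wild-type, 435 to 2004 in the knockout, 1 to 1624 for genotype under corn oil, 21 to 73 under TCDD and 0 to 546 for the interaction. Lists called ranged from 4 to 12, 4 to 6, 3 to 10, 5 to 9 and 4 to 9 in the same order.

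For TCDD in the wild-type (27), the count was 13 with only the arrays of both groups, 52 without the lowest 50% of probe sets, 47 with array weights, 12 at an adjusted p below 0.01 and 6 with the clock index. In the knockout (1303) it was 184 with only the arrays of both groups, 2515 with array weights, 813 with a fold of at least 1.5, 293 at an adjusted p below 0.01, 272 with the clock index and 533 against wild-type corn oil. Against that control Ccnd1 reversed, to 0.18 without a call. The median of cholesterol synthesis in the wild-type ranged from -0.39 to 0.06 when 1 array was left out, and reversed, without a call, when that was wild-type TCDD replicate 1.

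For genotype under corn oil (457), limma called 0 with only the arrays of both groups (3842 at an unadjusted p under 0.05) and 0 with the clock index (3332). The index did not overlap between the corn oil groups (-1.86 to -1.09 in the wild-type, -0.015 to 1.77 in the knockout). Its fit therefore cannot separate the clock from genotype, and the 0 decides nothing about either. The count was 819 and 1197 without the lowest 25% and 50% of probe sets, 777 with 1 symbol, 1734 with array weights and 1 at an adjusted p below 0.01. Under TCDD (56) limma called 0 with only the arrays of both groups (2864 unadjusted), 88 and 85 without the lowest 25% and 50%, 110 with 1 symbol, 176 with array weights, 20 at an adjusted p below 0.01 and 31 with the clock index.

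For the interaction (37), the count was 61 after quantile normalization, 149 and 396 without the lowest 25% and 50%, 162 with 1 symbol and 693 with array weights. Limma called 0 at an adjusted p below 0.01 (3446 at an unadjusted p under 0.05) and 0 with the clock index (2426). The mean index differed with TCDD by 1.60 in the wild-type and by -1.95 in the knockout, so the same limit holds for that fit.

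The labels do not say whether a replicate number marks a shared litter, batch or day. Residuals of 18 same-number pairs correlated at -0.208 to 0.114 and of 36 other pairs at -0.107 to 0.163. No pairing was seen in these values, but they do not exclude one. With the numbers as a block, the counts were 15, 860, 0 (4298 at an unadjusted p under 0.05 in limma), 43 and 0 (3246), and the shared TCDD calls 12.

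Lists called with an estimated correlation, directional fry and fry in either direction were 3, 3 and 3 against 11 in the wild-type, 1, 3 and 17 against 5 in the knockout, 0, 0 and 16 against 5 for genotype under corn oil, 1, 3 and 8 against 7 under TCDD, and 0, 2 and 11 against 5 for the interaction. Shared TCDD calls (23) were 10 at an adjusted p below 0.01. The odds ratio for neighbours of Tiparp (1.08) was 2.70, 1.76 and 0.689 with 25, 50 and 200 neighbours, and Tiparp under TCDD was -3.68 and -3.72 after quantile normalization and median centring. Tiparp has 1 probe set, so the alternative of every probe set gave no value. Among values of single genes over all alternatives, 1048 kept their side of the threshold, 455 lost the call, 6 gained it and 1 reversed, and among lists, by the direction of the test, 309 kept their side, 111 lost the call, 5 gained it and 1 reversed. Medians also changed sign without 1 array for macrophage and Kupffer cell markers (up to 0.05) and p53 targets (up to 0.03) in the wild-type, NRF2 genes in the interaction (-0.08 to 0.18) and glucose metabolism in the knockout (-0.30 to 0.13).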

Other observations

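The tests of the clock index and of glucocorticoid exposure and the markers shown per array were chosen only after the data were seen.

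Clock genes differed between arrays. The mean clock index was -1.45 ± 0.39 in wild-type corn oil, 0.16 ± 1.25 in wild-type TCDD, 1.11 ± 0.98 in knockout corn oil and -0.84 ± 1.15 in knockout TCDD (SD, n = 3 each). Between genotypes under corn oil the difference of 2.55 had an exact permutation p of 0.1, the smallest that 3 against 3 arrays allow. Dbp (2.36; adjusted p = 0.136), Arntl (-1.97; adjusted p = 0.137) and Npas2 (-1.80; adjusted p = 0.109) were not called there. The acute phase gene Lcn2 read 13.89, 13.87 and 13.08 on the knockout corn oil arrays and 10.94, 10.61 and 13.38 on the wild-type corn oil arrays, so the groups overlapped. Of the 27 lists, 11 were not called by camera with the preset correlation in any comparison, which were bile acids, CAR and PXR targets, cholangiocytes, the clock, female-biased genes, glucose, lipid uptake and droplets, NAD, neutrophils, pancreas and fat, and the PARP family. Fry in either direction, which asks whether members change at all, did call several of these, among them CAR and PXR targets (adjusted p = 5.83e-07), pancreas and fat (4.04e-06), lipid uptake and droplets (0.000226) and the clock (0.0217) for TCDD in the knockout.

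Glucocorticoid exposure was weighed as a hypothesis for the genes higher in the knockout under corn oil, because Fkbp5 and Per1, both glucocorticoid targets and both left out of the list tested, had their highest means there. The median of 8 measured of 10 glucocorticoid-induced genes was 0.0233, with 4 above 0, from -1.24 for Tsc22d3 to 1.93 for Mt1. The list was not called by camera of limma. The bound set before this test was run, a camera p of 0.05 or more, was wrong, because a missed p excludes nothing, and members that go both ways decide nothing. Glucocorticoid exposure may or may not differ between these groups.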
